A study of Mus musculus with 10 samples.

How the data were processed

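Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open chromatin and the cut sites are sequenced, in MC3T3-E1 cells, a mouse osteoblast line. The labels give 4 groups of 2 libraries: untreated cells (none), cells given TNFa, cells given BMP4, and cells given both. A further 2 libraries of sonicated DNA served the authors as background. The titles of the TNFa libraries alone also carry p65. The labels do not say why, so it is open whether these libraries were made like the others, and every value against the TNFa group carries that doubt. The labels number the libraries of each group 1 and 2, put all libraries in 1 batch, and do not say whether they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The treatment protocol in the labels has TNFa added at 10 ng/ml for 30 min before BMP4 at 10 ng/ml for 3 h, whereas the sample labels give 3 h for TNFa, so the length of the TNFa treatment is uncertain.

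Per the submitters' processing notes, Trimmomatic 0.39, Bowtie2 2.5.1, Picard 2.25.1, deepTools 3.5.1, HOMER 4.11 and the mouse build mm10 were used. Whether reads were shifted for the transposase offset is not given in the sources used here. Per the file headers, the authors called peaks with HOMER on the pooled replicates of each group against both background libraries. They kept windows of 125 bp with an adjusted p under 0.05 against background, so a list has no replicate of its own. The deposited lists give each peak's position, its nearest gene and annotation, a peak score set by HOMER, a log2 fold change over background and its p-value, and 4 columns of values per library. The peak score was not used in a test. Per the file headers these last columns are tag counts, but the deposited values are regularised log2 values (the rlog of DESeq2), fitted by the authors in each list separately. They are therefore not comparable between lists as they stand.

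The rlog equation was solved for the tag counts behind the values, with 4 fitted constants per list. Of the values, 99.94% in the untreated list, 99.99% in the TNFa list, 99.25% in the BMP4 list and 100% in the list of both came out within 0.1 of a whole number. With the constants moved by 5%, 16.5% to 19.1% did. In windows with identical coordinates in a pair of lists, 100% of the recovered background counts were equal, although the deposited values of the same background libraries differed. All values of a window came out so close in 97.03% of windows of the BMP4 list and in 99.76% to 99.99% in the other lists. On 4000 simulated windows per list the solution returned 100% of the counts exactly. The simulated values were made with the same equation and constants. This checks the solution only, not whether the equation holds for the deposited values.

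Windows were matched across the 4 lists where they overlapped by at least 50% (63 bp), which left 14471 windows, 2914 of them with identical coordinates and with a median shift of 8 bp. Each group's counts come from its own list. Windows with a count equivalent to at least 10 in at least 2 libraries and a total of at least 15 were tested, 14416 in all. The design fixed before the data were examined named a negative binomial quasi-likelihood test on deposited counts. The deposited unit is log2. The planned test was not run on the recovered counts, which would have allowed it. In its place limma 3.58.1 (R 4.3.3) was used, with a mean-variance trend on log2 values of the recovered counts. These were scaled by a trimmed mean of M-values (TMM), with a pseudocount of 2, and fitted over all 8 libraries with group as the only term. Levels of single windows are in counts-per-million (CPM) of the tags in tested windows after TMM, as mean and SD of 2 libraries. Fold changes are on the log2 scale and understate the change of low windows. P-values are two-sided and adjusted by Benjamini-Hochberg over windows.

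Gene lists fixed before the data were examined (14 of them) were tested with camera at a preset correlation of 0.01, adjusted over the 14 lists of a comparison, with camera at an estimated correlation and fry beside it. They hold NF-kB targets, BMP/SMAD targets, osteoblast genes, cell death inhibitors, cell death effectors, AP-1 and immediate early genes, interferon response genes, matrix remodelling genes, Wnt pathway genes, and markers of adipocytes, chondrocytes, haematopoietic cells and muscle or endothelium, with housekeeping genes as controls. A window belongs to a gene by the nearest-gene column of the files. Older gene names were matched through the RefSeq table. A first version of that matching had put Igf2bp1 and Loxl3 on lists through synonyms that are other genes' official symbols. This was corrected after the list tests had been seen, and the values with the first version are given as an alternative. The named windows follow a rule fixed in advance. It takes up to 12 windows per direction past an adjusted p of 0.05, or, where fewer than 5 pass, the 3 with the smallest p, stated as not passing. It adds up to 4 windows with the smallest p per list, and for regions in some lists only the 5 with the most tags. Some windows that the rule names are not reported here.

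Regions were formed by overlap of the 4 lists, and the share of each gene list in each pattern of lists was tested with Fisher's exact test over 56 tests. After 0 windows had passed, several tests were added. These are the comparisons that average TNFa over BMP4 and BMP4 over TNFa, the first or the first 2 principal components as covariates, thinning of the libraries to equal tags in the matched windows (their total tags stay unequal), a score per list and library, and windows within 500 bp joined. A covariate estimated from the residuals of the group fit was tried and not used, since it removes spread between replicates by construction. Confidence intervals of shares are 95% Wilson intervals and cover counting error only.

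The window test was tested on simulated counts for TNFa vs none in 14416 windows. At the spread measured between replicates (dispersion 0.178) it recovered 14% of windows changed 4-fold and 70% of those changed 8-fold, and at a dispersion of 0.02 it recovered 98% and 100%. A simulated set of 50 windows raised 1.5-fold gave a camera p of 2.25e-06, and 3 of 100 unchanged sets had a p under 0.05. Simulated windows varied independently of each other, unlike those of real libraries. The simulation therefore does not show that camera p-values hold for the real lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for the other steps. No genome sequence was used here, so motif tests and a correction for GC content were not run.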

Results

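ATAC-seq was performed on MC3T3-E1 cells, a mouse osteoblast line, to ask how the inflammatory cytokine TNFa and the bone morphogenetic protein BMP4, alone or together, alter chromatin accessibility. The series concerns the protection of cells against inflammatory death by BMP signalling. There were 2 libraries per group. The TNFa libraries alone have p65 in their titles, for a reason the labels do not give, so comparisons with that group assume that they were made like the others. Total tags (M) were 30.1 and 29.1 in untreated cells, 16.5 and 19.7 with TNFa, 26.0 and 27.9 with BMP4, and 21.8 and 18.8 with both, so the libraries given TNFa, alone or with BMP4, were the shallower ones. The authors' lists hold 26230 peaks for untreated cells, 23288 for TNFa, 24525 for BMP4 and 23745 for both factors. Promoters made up 32.0%, 35%, 31.8% and 34.4% of them. The share of a library's tags inside its own list was 5.98% ± 1.22 (SD, n = 2) in untreated cells, 5.24% ± 0.52 with TNFa, 6.44% ± 2.21 with BMP4 and 5.39% ± 0.82 with both, against 0.38% to 0.40% of background tags in the same windows. It ran from 4.81% (95% Wilson interval 4.80 to 4.82) in replicate 1 of the combined treatment to 8.00% (7.99 to 8.01) in BMP4 replicate 2, and intervals cover counting error only.

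Of 35534 regions in any list, 15119 (42.5%) were in all 4. Another 1485 were in both TNFa lists only, 2615 in both lists without TNFa only, 913 in both BMP4 lists only and 1008 in both lists without BMP4 only. With the lists brought to the length of the shortest, 1962 were in both TNFa lists only and 2210 in both lists without TNFa only. Accessibility was compared in 14416 windows found in all 4 lists, so a site that opened from nothing or closed fully is outside the comparisons of windows. Replicates differed by far more than sampling noise, with a chi-square per window of 8.86 to 34.4. Their log2 values correlated across windows, which are not independent, at 0.59 in untreated cells, 0.659 with TNFa, 0.393 with BMP4 and 0.749 with both. Some libraries of different groups correlated more closely than these, as untreated replicate 2 and BMP4 replicate 2 (0.953), BMP4 replicate 1 and replicate 1 of the combined treatment (0.933), and untreated replicate 1 and replicate 2 of the combined treatment (0.903). Other such pairs correlated less, down to 0.378 between BMP4 replicate 2 and replicate 1 of the combined treatment. The first principal component held 63.3% of the variance, and replicate 2 lay above replicate 1 on it in each group. Untreated replicate 2 (94.3) and BMP4 replicate 2 (95.9) were far from their partners (-15.4 and -71.5). The TNFa libraries lay at -58.5 and 41.8, and those of the combined treatment at -73.9 and -12.6.

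**Figure D1:**
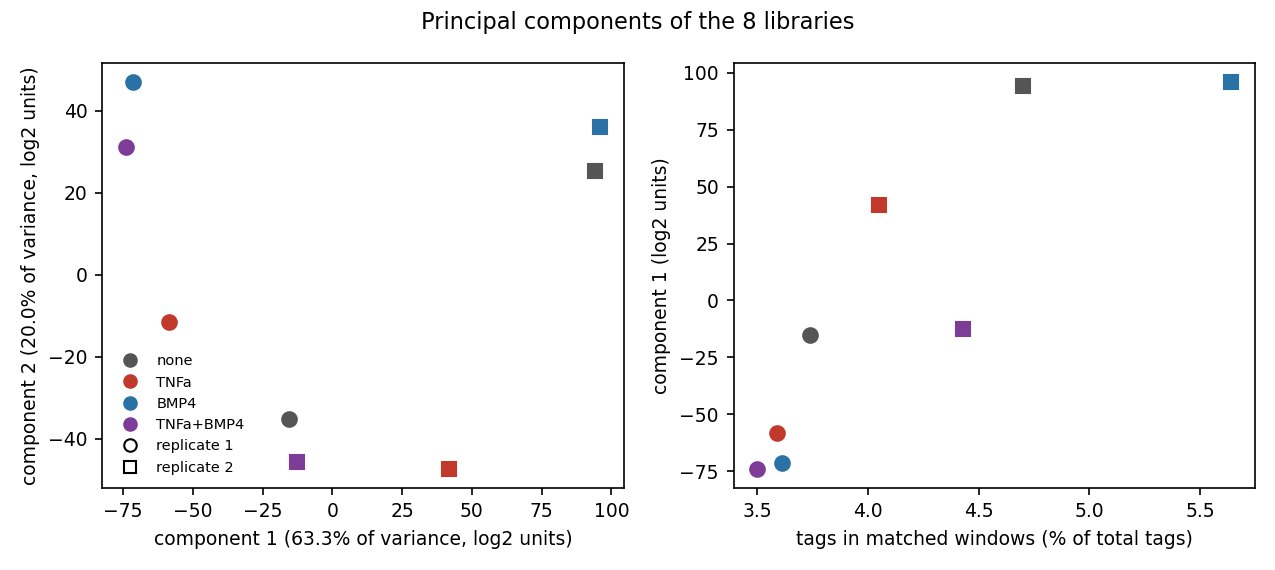
Principal components of the 8 libraries from log2 accessibility of 14416 windows, with colour for the group and symbol for the replicate number. Left, component 1 (63.3% of variance) against component 2 (20%); right, component 1 against the percentage of a library's tags in matched windows, which was 4.70% in untreated replicate 2 and 5.64% in BMP4 replicate 2.

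TNFa was compared with no treatment to ask what the cytokine alone does to chromatin. Windows of NF-kB targets, the genes that TNFa signalling switches on through p65, rose as a group. Of 50 windows at 22 genes, 39 lay above 0, and the median log2 fold change was 0.58 (camera adjusted p = 5.01e-09; adjusted p = 0.105 with an estimated correlation and 0.0963 with fry). Among them, a window upstream of Ccl2, a chemokine that draws monocytes, held 133 ± 61.4 CPM (normalised tags-per-million in the tested windows; SD, n = 2) with TNFa and 28.4 ± 13.5 without. This is a log2 fold change of 2.24 ± 0.63 (SE). Nfkbia, which encodes the inhibitor of NF-kB, had a distal window at 1.90 ± 0.78, the cytokine gene Lif one at 1.61 ± 0.61 and the chemokine gene Ccl5 one at 1.31 ± 0.57, and none of these passed on its own. Interferon response windows also rose, 11 of 14 above 0 at a median of 0.49 (adjusted p = 0.0209; adjusted p = 0.24 with an estimated correlation and 0.0632 with fry). That call was lost without untreated replicate 1 (adjusted p = 0.369) or TNFa replicate 2 (0.326). A window of Irf1 was at 0.75 ± 0.51 and one of the antigen transporter gene Tap1 at 0.92 ± 0.70. Of this list, Irf1 and Cxcl10 are also on the NF-kB list.

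The windows with the smallest p in this comparison lay elsewhere. An intergenic window at -11320 bp from the start of Pdgfb, the gene of a platelet-derived growth factor chain (mm10 chromosome 15, 80026235 to 80026359), held 179 ± 69.8 CPM with TNFa and 31.6 ± 2.8 without (SD, n = 2), a log2 fold change of 2.45 ± 0.56 (SE). A window in intron 6 of Mapt, the gene of the microtubule protein tau (chromosome 11, 104303716 to 104303840), was at 105 ± 7.1 against 24.1 ± 4.2. An intergenic window near the ubiquitin ligase gene Herc1 (chromosome 9, 66276901 to 66277025) differed by 2.84 ± 0.75. Lower values were found in intron 1 of the pseudogene Speer5-ps1 (chromosome 10, 44170863 to 44170987; 21 ± 0.1 against 98.1 ± 10.3). They were also found in intron 1 of Vgll4, a cofactor of TEAD factors (chromosome 6, 114963817 to 114963941), at -2.14 ± 0.57, and in a distal window of the repressor gene Prdm1 (chromosome 10, 44716741 to 44716865) at -1.82 ± 0.48. All 6 had a limma adjusted p of 1.

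Osteoblast genes did not pass between TNFa and none, with 27 of 62 windows above 0, a median of -0.07 and an adjusted p of 0.439. Runx2, the master regulator of osteoblasts, had an intronic window at -1.39 ± 0.59. Matrix remodelling windows (35 of 52 above 0, median 0.13, adjusted p = 0.238) and AP-1 and immediate early windows (53 of 84, median 0.15, adjusted p = 0.238) did not pass. Nor did cell death effectors (17 of 27, median 0.08, adjusted p = 0.484), or cell death inhibitors, whose median was 0.08 while their mean was -0.04 (adjusted p = 0.933). The AP-1 list passed in 1 of 29 alternatives, with windows within 10000 bp of a start site (camera adjusted p = 0.0321). Cell death effectors passed in 2 of 28, with a lowest adjusted p of 0.0197. Chondrocyte markers (3 of 11 above 0, median -0.37) and muscle or endothelial markers (0 of 9, median -0.23) both had an adjusted p of 0.0504, and passed in 14 and 8 of 28 alternatives (from 0.00347 to 0.38 and from 0.0305 to 0.746). The chondrocyte list passed without untreated replicate 2 (0.027), TNFa replicate 1 (0.0259) or BMP4 replicate 1 (0.0419) or 2 (0.0433), and the muscle or endothelial list without BMP4 replicate 1 (0.0419) or 2 (0.0433). Housekeeping windows lay higher too, 28 of 38 at a median of 0.25 (adjusted p = 0.0601). This control list passed in 5 of 29 alternatives (0.0249 to 0.695), lowest with a mean count of at least 30, and also with total tags (0.0433) or without BMP4 replicate 1 (0.0419) or 2 (0.0433).

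In limma 0 of 14416 windows passed for TNFa vs none, with 151 at an unadjusted p under 0.05 (140 with voom weights) where chance gives 721, and 0 passed adjusted over the list alone in any list. With group as the only term, a difference shared by the replicate numbers counts as spread. Here and in the later comparisons, 0 passing therefore does not show an absence of change. With the replicate number as a block, 862 windows had an unadjusted p under 0.05 and 0 passed. Over 29 alternatives the adjusted p ran from 2.64e-12 to 0.105 for NF-kB targets and from 0.00222 to 0.369 for the interferon list.

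Regions called in some lists only were tested too. Of 1485 regions found in both TNFa lists only, 24 belonged to NF-kB targets where 6.6 would be expected (odds ratio 4.19, Fisher's exact adjusted p = 2.29e-06). They lie at Bcl3, Ccl2, Ccl7, Cd44, Csf1, Icam1, Lif, Nfkbia, Nfkbie, Tnfaip3, Tnfrsf9, Tnip1 and Vcam1. No other gene list passed in these patterns of lists. For the 2615 regions in both lists without TNFa only, 8 NF-kB regions stood against 11.6 expected. These 8 lie at Cd44, Csf1, Il6, Lif, Nfkbia, Tnfaip3, Traf1 and Vcam1, all but Il6 and Traf1 also named above. The test counts regions at the same gene as independent. The regions with the most tags in both TNFa lists only were near Sertad2, 4932412D23Rik, Tns1, Mcl1 and Specc1. The region at Mcl1, an inhibitor of apoptosis, lies at -8039 bp from its start (chromosome 3, 95650620 to 95650744), with 301 and 339 tags in the TNFa libraries and 376 and 372 in those with both factors. The Sertad2 region has a partner called in both lists without TNFa (chromosome 11, 20477562 to 20477686 in the BMP4 list), so its place in these patterns reflects where the window was centred. Of the 1485 regions, 43.7% had a window of another list within 500 bp. With such windows joined, a step added after the data were seen, 840 regions remained and NF-kB targets had 16 against 3.3 expected (adjusted p = 1.05e-05). Mcl1 and Cd44 were then no longer among the genes of this pattern. Among joined regions in both lists without TNFa only, chondrocyte markers had 9 against 2.9 expected (adjusted p = 0.0499), at Col11a2, Comp, Hapln1, Sox5, Sox6 and Sox9.

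**Figure D2:**
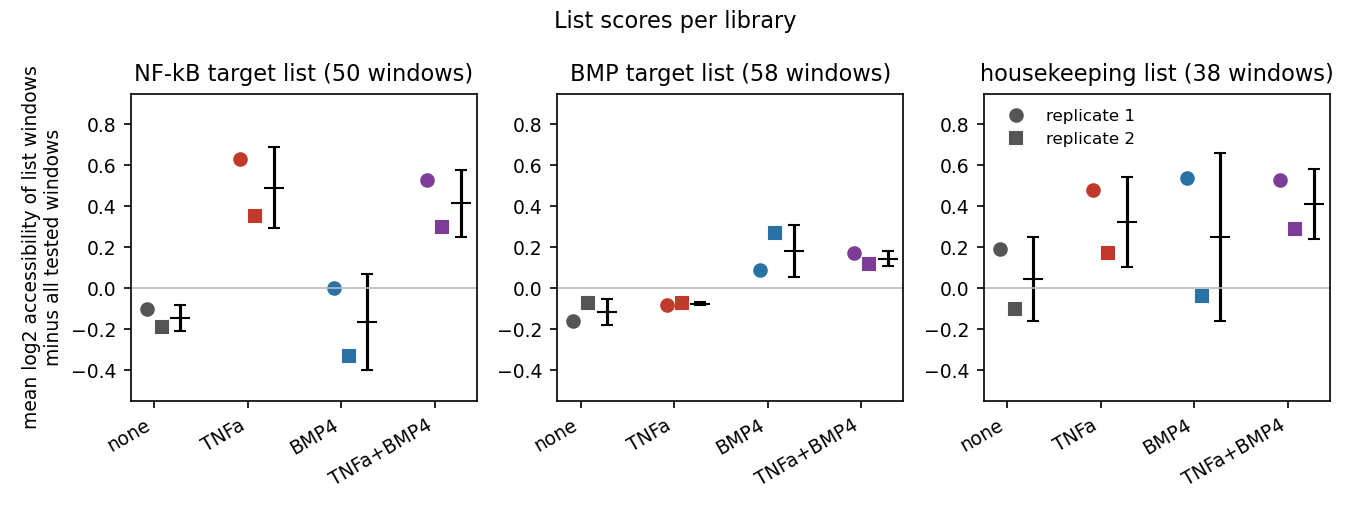
Score of the NF-kB, BMP and housekeeping lists in each of the 8 libraries, as the mean log2 accessibility of the list's windows minus that of all tested windows; points are libraries, and the line is the mean with its SD. The NF-kB score ran from 0.30 to 0.63 in the 4 libraries with TNFa and from -0.33 to 0.00 in those without, and the BMP score from 0.09 to 0.27 with BMP4 and from -0.16 to -0.07 without.

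BMP4 was compared with no treatment to ask what the growth factor alone does. Windows of BMP targets, the genes that SMAD proteins switch on, rose as a group, 39 of 58 above 0 at a median log2 fold change of 0.36 (camera adjusted p = 0.000922; adjusted p = 0.105 with an estimated correlation and 0.126 with fry). The promoter of Id3, an inhibitor of helix-loop-helix factors (chromosome 4, 136143641 to 136143765), held 329 ± 54.9 CPM (SD, n = 2) with BMP4 and 134 ± 50.1 without. Its log2 fold change was 1.34 ± 0.51 (SE). A distal window of Atoh8 was at 1.06 ± 0.54, the promoter of the inhibitory Smad6 at 1.20 ± 0.64 and a window near Id4 at 1.10 ± 0.64. Among markers of cartilage cells, intronic windows of the transcription factor genes Sox6 (1.46 ± 0.64) and Sox5 (1.44 ± 0.67) lay higher, and the chondrocyte list had 9 of 11 windows above 0 at a median of 0.37 (adjusted p = 0.0612). That list passed in 7 of 28 alternatives (0.00936 to 0.697), among them without TNFa replicate 1 (0.0419) or 2 (0.0459). Muscle and endothelial markers lay as high (7 of 9 above 0, median 0.38, adjusted p = 0.0775) and passed in 4 of 28 alternatives (0.00184 to 0.948), with the lowest value without BMP4 replicate 1. Housekeeping windows had a median of 0.22 (27 of 38 above 0, adjusted p = 0.228).

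Outside the lists, an intergenic window near the uncharacterised transcript A730020M07Rik (chromosome 3, 121604641 to 121604765) was at 223 ± 63.2 CPM against 62.8 ± 2.9 (SD, n = 2), a log2 fold change of 1.80 ± 0.51 (SE). Distal windows of Fign, which severs microtubules (1.68 ± 0.49), and Marc1 (1.80 ± 0.58) had the next smallest p of the higher windows. Of the lower ones, the smallest p were those of windows assigned to Artn, a ligand of the GDNF family (-1.62 ± 0.51), to Gm4668 (-1.27 ± 0.50) and to Dnmbp, at its promoter (-1.37 ± 0.58). In limma all 6 had an adjusted p of 1. Osteoblast windows showed a median of 0.07 (35 of 62 above 0, adjusted p = 0.68), with a distal window of the matrix gene Postn at 0.95 ± 0.47 and one at the end of the collagen gene Col1a2 at 0.81 ± 0.49. Windows of NF-kB targets had a median of 0.02, with 27 of 50 above 0 (adjusted p = 0.867). Adipocyte windows had a median of 0.21, a mean of 0.03 and a lower rank in the test (adjusted p = 0.913). Wnt pathway windows (14 of 22 above 0, median 0.13, adjusted p = 0.68) and haematopoietic marker windows (12 of 18, median 0.18, adjusted p = 0.573) did not pass either.

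For BMP4 vs none, 0 windows passed in limma, 28 had an unadjusted p under 0.05 (32 with voom weights), and 0 passed adjusted over the list alone. The call of the BMP list was lost without untreated replicate 1 (adjusted p = 0.129), untreated replicate 2 (0.0524) or BMP4 replicate 2 (0.489), and in the windows with identical coordinates (0.405), over a range of 2.5e-05 to 0.489. Regions in both BMP4 lists only held 9 of BMP targets where 3.9 would be expected, at Atoh8, Hes1, Id3, Rgs4, Smad7 and Smad9 (Fisher's exact adjusted p = 0.222). With windows within 500 bp joined they held 5 against 2.1 expected, at Atoh8, Hes1, Id2 and Smad9 (adjusted p = 0.468). The regions of that pattern with the most tags were near Gadd45b, a stress response gene (chromosome 10, 80936380 to 80936504 in the BMP4 list, with 396 and 762 tags), Cacna1g, Ankhd1, Thoc6 and Atp5g1. Those at Cacna1g and Atp5g1 have partners called in both lists without BMP4, and 49.2% of the pattern's regions had a window of another list within 500 bp.

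**Figure D3:**
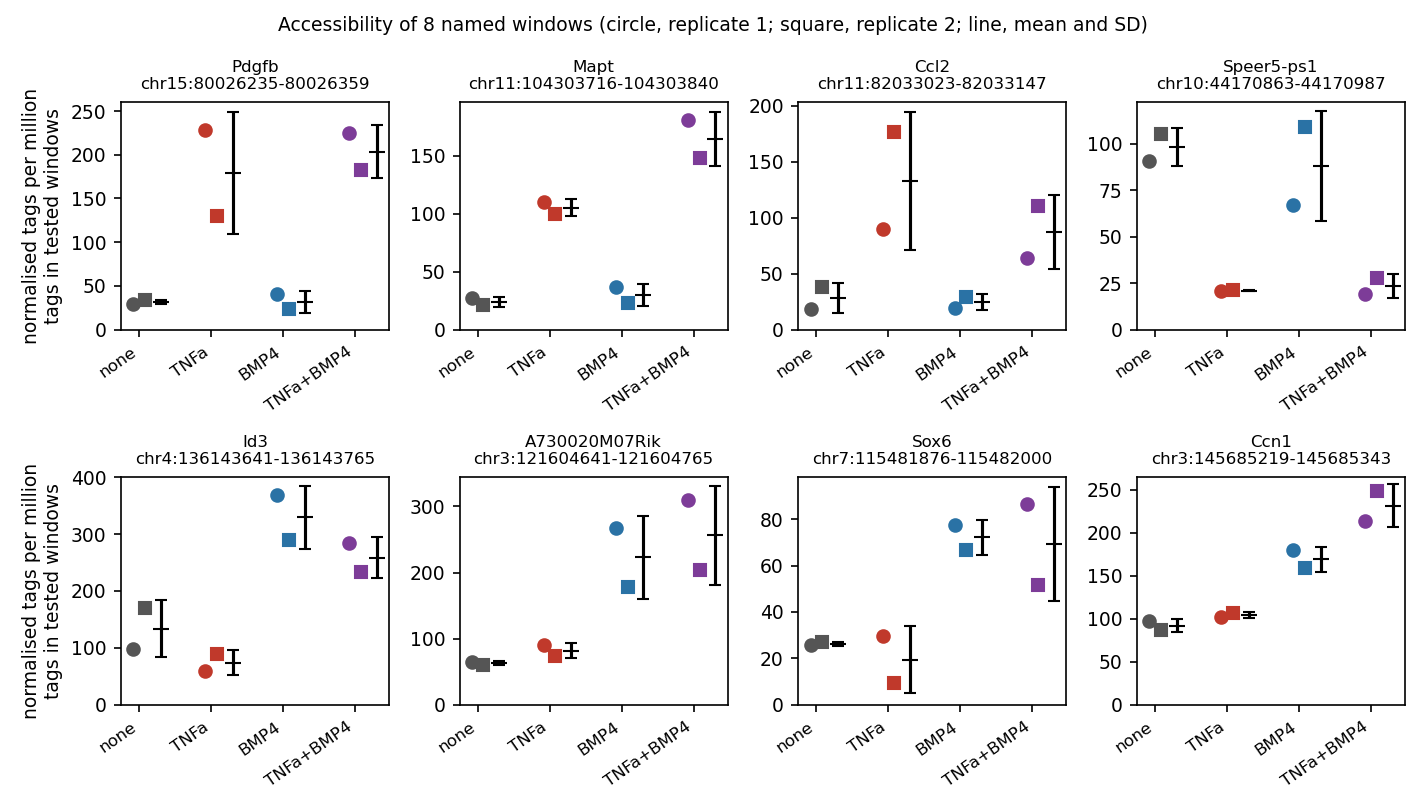
Normalised CPM (vertical axis) in 8 named windows, by group; circles and squares are replicates 1 and 2, and the line is the mean with its SD (n = 2). Pdgfb, Mapt and Ccl2 lie higher in the libraries with TNFa and Speer5-ps1 lower, while Id3, A730020M07Rik, Sox6 and Ccn1 lie higher in those with BMP4; none passed in limma in a planned comparison.

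Cells given both factors were compared with untreated cells. NF-kB target windows rose, 35 of 50 above 0 at a median log2 fold change of 0.48 (camera adjusted p = 0.000488), and so did BMP target windows, 39 of 58 at a median of 0.17 (adjusted p = 0.0435). With an estimated correlation both lists had an adjusted p of 0.209 (0.131 with fry), and the BMP call was lost in 15 of 29 alternatives. The window of Mapt reached 165 ± 23.3 CPM (SD, n = 2), a log2 fold change of 2.78 ± 0.52 (SE), and that of Pdgfb 203 ± 30.1, a change of 2.68 ± 0.56. An intronic window of the noncoding Wincr1 (chromosome 4, 89057054 to 89057178) was at 74.6 ± 4.9 against 18.4 ± 1.8. Lower values were seen at Speer5-ps1 (-2.09 ± 0.52), at a window near Kcns1, a potassium channel subunit gene (-2.06 ± 0.52), and at a distal window of Prok2, the gene of the secreted prokineticin 2 (-1.91 ± 0.48). These 6 windows had a limma adjusted p of 0.897. Housekeeping windows again lay higher, 29 of 38 at a median of 0.29 (adjusted p = 0.0897).

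In this comparison 0 windows passed in limma and 357 had an unadjusted p under 0.05 (360 with voom weights), with 0 adjusted over the list alone. The NF-kB call was lost without untreated replicate 1 (adjusted p = 0.0813; range 1.32e-06 to 0.209). The BMP call was lost without untreated replicate 1 (0.465), BMP4 replicate 1 (0.077) or 2 (0.0791), or replicate 1 (0.0775) or 2 (0.144) of the combined treatment (adjusted p from 1.92e-05 to 0.966 over the alternatives). In windows with identical coordinates its mean difference was -0.03 (adjusted p = 0.966).

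The comparison of both factors with TNFa alone asks what BMP4 adds to cells that meet TNFa, the setting named in the series title. Windows of BMP targets rose, 34 of 58 above 0 at a median log2 fold change of 0.12 (camera adjusted p = 0.01; adjusted p = 0.163 with an estimated correlation and 0.243 with fry). The Id3 promoter held 258 ± 36.0 CPM with both factors and 73.9 ± 21.6 with TNFa alone (SD, n = 2), a log2 fold change of 1.83 ± 0.51 (SE). Upstream of Id2 a window was at 1.26 ± 0.54 and the promoter of Id1 at 1.11 ± 0.61, whereas a distal window of Fst, which encodes the BMP and activin antagonist follistatin, was at -1.12 ± 0.66. Chondrocyte marker windows rose at a median of 0.62 (7 of 11, adjusted p = 0.00454; adjusted p = 0.163 with an estimated correlation, 0.0192 with fry and 0.472 within 10000 bp of a start site). Members included Sox6 (2.03 ± 0.64; chromosome 7, 115481876 to 115482000) and Sox5 (1.45 ± 0.67), the partners of Sox9 in cartilage. Muscle and endothelial marker windows also rose, 9 of 9 above 0 at a median of 0.36 (adjusted p = 0.00454; adjusted p = 0.30 with an estimated correlation and 0.68 with fry). The endothelial genes Pecam1 and Cdh5 had windows at 0.91 ± 0.51 and 1.09 ± 0.69. Against untreated cells, chondrocyte and muscle or endothelial markers had medians of 0.05 and 0.13 with both factors (camera adjusted p = 0.785 each). These medians were -0.37 and -0.23 with TNFa alone and 0.37 and 0.38 with BMP4 alone. The rise over TNFa alone thus includes the lower values of the TNFa group. Relative to TNFa alone, NF-kB target windows did not pass, with 23 of 50 above 0 and a median of -0.03 (adjusted p = 0.542). They passed, as lower, in 4 of 29 alternatives (0.00557 to 0.872). These were without TNFa replicate 2 (0.0179) or replicate 1 of the combined treatment (0.0331), and with 1 (0.0342) or 2 (0.00557) principal components as covariates, chosen after the data were seen.

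Windows of cell death effectors fell with both factors relative to TNFa alone, 20 of 27 below 0 at a median of -0.22 (camera adjusted p = 0.0466; adjusted p = 0.233 with an estimated correlation and 0.68 with fry). Against untreated cells they did not pass with both factors (12 of 27 above 0, median -0.03, camera adjusted p = 0.626). The list's score was 0.07 and 0.35 in untreated libraries, 0.33 and 0.39 with TNFa and 0.14 and 0.11 with both. The call relative to TNFa alone held in 10 of 28 alternatives only (adjusted p from 0.0046 to 0.68). Members had small values, as at the gene of the pro-apoptotic Pmaip1 (-0.70 ± 0.52) and at Fadd, an adaptor of death receptors (-0.74 ± 0.65). Gsdme, a pore-forming gasdermin gene, was at 0.59 ± 0.53. The call was lost without TNFa replicate 1 (0.315) or 2 (0.108), BMP4 replicate 1 (0.0632) or 2 (0.0618) or replicate 2 of the combined treatment (0.419). With Igf2bp1, which was first matched to this list by a synonym, the adjusted p was 0.0666. Cell death inhibitors had a median of 0.04 (15 of 26 above 0, adjusted p = 0.684), with intronic and promoter windows of Bcl2l1 and Ikbkg at 0.59 ± 0.46 and 0.60 ± 0.51.

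Among single windows, Prdm1 (41.4 ± 6.1 against 13.7 ± 2.0 CPM, SD, n = 2) and A730020M07Rik (256 ± 74.7 against 81.6 ± 11.2) followed Id3. Windows in introns of Cpq, a carboxypeptidase gene (-1.63 ± 0.51), and Abtb2 (-1.45 ± 0.47) and the window of Prok2 (-1.39 ± 0.48) were lower, and all had a limma adjusted p of 1. A distal window of Ccn1, a matricellular growth regulator gene, was at 1.14 ± 0.46. In all 0 windows passed, 37 had an unadjusted p under 0.05 (34 with voom weights) and 0 passed adjusted over the list alone. Without TNFa replicate 1 BMP targets, chondrocyte markers and muscle and endothelial markers had adjusted p of 0.315, 0.23 and 0.23, and without replicate 2 of the combined treatment 0.142 each. In windows with identical coordinates BMP targets and muscle or endothelial markers had 0.816. The range over alternatives was 5.49e-05 to 0.816 for BMP targets, 0.000671 to 0.472 for chondrocyte markers and 0.000174 to 0.816 for muscle and endothelial markers.

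Both factors were also compared with BMP4 alone. NF-kB target windows rose, 40 of 50 above 0 at a median log2 fold change of 0.34 (camera adjusted p = 1.49e-05; adjusted p = 0.247 with an estimated correlation and 0.185 with fry; range 7.76e-12 to 0.247). The windows with the smallest p were again Mapt (2.50 ± 0.52, SE) and Pdgfb (2.72 ± 0.56), followed by an intronic window of Bahcc1 (chromosome 11, 120251480 to 120251604) at 274 ± 44.5 CPM against 72 ± 11 (SD, n = 2). Lower values lay in intron 1 of Tom1l2, whose product takes part in vesicle transport (42.4 ± 2.7 against 207 ± 49.7), near E330011O21Rik (-2.10 ± 0.56) and at Speer5-ps1 (-1.89 ± 0.52), all with a limma adjusted p of 0.989. Interferon response windows had a median of 0.65 (9 of 14 above 0, adjusted p = 0.154), osteoblast windows -0.18 (adjusted p = 0.321) and BMP target windows -0.09 (adjusted p = 0.934). Again 0 windows passed, 230 had an unadjusted p under 0.05 (238 with voom weights), and 0 passed adjusted over the list alone.

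**Figure D4:**
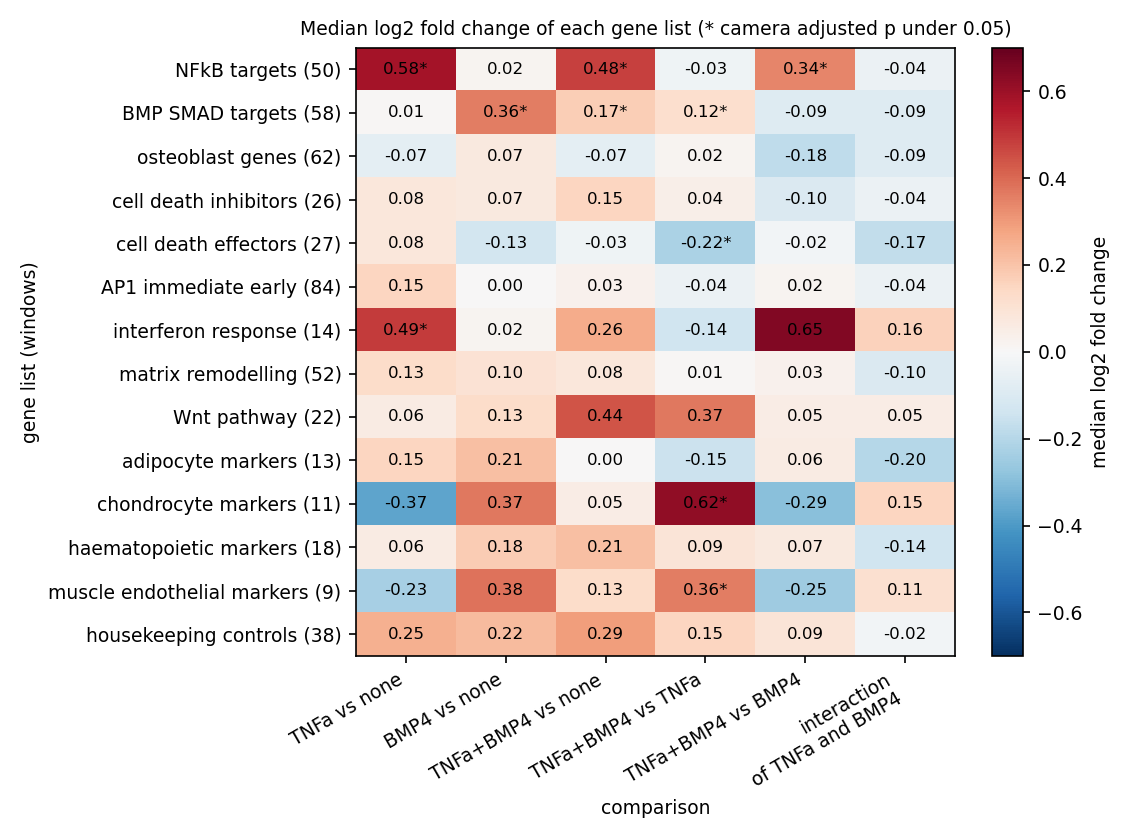
Median log2 fold change of the windows of each of the 14 gene lists (vertical axis, with their number of windows) in the 6 planned comparisons (horizontal axis); an asterisk marks a camera adjusted p under 0.05 at the preset correlation. The NF-kB list is at 0.58, 0.48 and 0.34 in the comparisons that add TNFa and the BMP list at 0.36 and 0.12 in those that add BMP4 to untreated cells or to TNFa.

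The interaction asks whether the response to TNFa differed with BMP4. The median of NF-kB target windows was -0.04 (22 of 50 above 0, camera adjusted p = 0.736) and that of BMP target windows -0.09 (23 of 58, adjusted p = 0.73). Cell death effectors had the smallest p of the lists (11 of 27 above 0, median -0.17, adjusted p = 0.559) and cell death inhibitors stood at -0.04 (adjusted p = 0.769). A window upstream of the growth gene Myc was at 1.28 ± 0.70 (SE), one with Cldn34-ps as nearest gene at 1.40 ± 0.80 and the promoter of Cp, the gene of ceruloplasmin, at 1.38 ± 0.81. Of the windows below 0, the smallest p were those at LOC666331 (-1.73 ± 0.85), Zbtb7c (-1.70 ± 0.90) and the mitotic kinesin gene Kif18a (-1.44 ± 0.77). In limma 0 windows passed and 0 had an unadjusted p under 0.05, with voom weights as well, and standard errors of this size leave differences of several fold undetectable.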

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

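The alternatives with principal components, deposited rlog values, a pseudocount of 0.5, voom weights, identical coordinates, 2 libraries left out together, thinning, list names matched through any synonym and windows joined within 500 bp, and the averaged comparisons, were chosen after the data were seen. The planned count test and its DESeq2 alternative, the GC correction and the motif tests were not run. In the 6 planned comparisons 0 windows passed in limma under any alternative run, leave-one-out included (0 to 0), with 151, 28, 357, 37, 230 and 0 at an unadjusted p under 0.05 (voom 140, 32, 360, 34, 238 and 0). Those counts moved without single libraries, over 35 to 363, 21 to 793 (highest without BMP4 replicate 2), 68 to 791, 11 to 121, 62 to 1809 (highest without BMP4 replicate 1) and 0 to 26. Of 4834 alternative values for 203 named windows and comparisons, 50 changed sign, 34 of them by leaving out a library. Where a group is left with 1 library, it is assumed to vary like the others. In simulated counts 14% of 4-fold changes were recovered, so independent spread of the measured size would limit these tests. The real replicate differences correlated between groups, as given below, and the simulation does not model that shared part. Scaling by total tags moved the median window by -0.15 for TNFa vs none, and changes are relative to that median. The cause was not tested for the values that follow.

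With a fold over background of at least 8, 18291 peaks remained for untreated cells, 15661 for TNFa, 19651 for BMP4 and 15754 for both, so the BMP4 list was then longer than the untreated one. At 90% overlap 8886 regions were in all 4 lists, 1555 in both BMP4 lists only and 1749 in both lists without BMP4 only. With windows within 500 bp joined, 840 were in both TNFa lists only and 494 in both BMP4 lists only. In matched windows the share of tags was 3.74% and 4.70% (untreated), 3.59% and 4.05% (TNFa), 5.64% (BMP4 replicate 2), and 3.5% and 4.43% (both). The averaged TNFa comparison passed 66 windows with the first principal component as a covariate and 310 with the first 2, and the averaged BMP4 comparison 1 with the first 2 (A730020M07Rik).

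Numbers of lists passing were 2 for TNFa vs none, 1 for BMP4 vs none, 2 for both vs none, 4 for both vs TNFa, 1 for both vs BMP4 and 0 for the interaction. With an estimated correlation each was 0, and with fry 0, 0, 0, 1, 0 and 0. For TNFa vs none it was 5 with total tags, 4 with loess, no filter, the first 2 components, rlog values, a pseudocount of 0.5 or without untreated replicate 2 and BMP4 replicate 2 together, and 1 in windows with identical coordinates. For BMP4 vs none it was 2 with total tags or 1 bp overlap, 3 when matched between the 2 compared lists or with 1 or 2 components, and 0 without those 2 libraries or at identical coordinates. For both vs none it was 1 with total tags, a mean count of 30, the compared libraries alone, 1 bp or 90% overlap, matching between the 2 lists, or identical coordinates. For both vs TNFa it was 1 within 10000 bp of a start site, 2 at 1 bp or 90% overlap, 3 with any synonym and 0 at identical coordinates. For both vs BMP4 it was 3 with the first component and 2 with the first 2. The averaged TNFa comparison (2) had 0 with an estimated correlation, 4 with fry, and 1 within 10000 bp, at a mean count of 30 or at identical coordinates. The averaged BMP4 comparison (3) had 0 with an estimated correlation or identical coordinates, 1 within 10000 bp and 5 with the first 2 components. Leaving out each library in turn gave 1 to 5 lists for TNFa vs none, 0 to 2 for BMP4 vs none, 0 to 2 for both vs none, 0 to 5 for both vs TNFa, 1 to 1 for both vs BMP4, 0 to 0 for the interaction, and 1 to 3 and 0 to 3 for the averaged TNFa and BMP4 comparisons.

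With the replicate number as a block, 0 windows passed in the planned comparisons, with 862, 528, 2552, 476, 1457 and 14 at an unadjusted p under 0.05 and a smallest adjusted p of 0.071, in both vs none. In the averaged TNFa comparison 332 passed, where 0 did without the block, 157 higher and 175 lower (3385 at an unadjusted p under 0.05, and 1850 in the averaged BMP4 comparison). Of the other splits, the one by the sign of the second principal component passed 1997. The split by replicate number, where the block drops out, passed 3753. Both follow structures of the samples, so the splits do not decide on chance, which is not excluded. Under this replicate block 2 lists passed for BMP4 vs none, 1 for both vs none and 1 for the averaged TNFa comparison. The differences between replicates 2 and 1 correlated at 0.105 to 0.764 between groups over windows, which are not independent, and replicate 2 had the higher share of tags in matched windows in 4 of 4 groups. This is a hint from the data at a shared condition, which the labels do not give, and the libraries were not treated as pairs.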

Other observations

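The tests in this part were chosen after the results of the planned comparisons were seen. For thinned libraries and for other splits of the NF-kB and BMP lists, the predicted outcomes were written before those tests. Averaged over BMP4, NF-kB target windows had a median log2 difference of 0.44 with TNFa (camera adjusted p = 1.4e-07; 0.077 with an estimated correlation and 0.0117 with fry). The list's score was 0.45 ± 0.16 in the libraries with TNFa and -0.16 ± 0.14 in those without (SD, n = 4), higher in 4 of 4 libraries (exact permutation p = 0.0286, the smallest that 70 splits can give; adjusted p = 0.16 over 28 tests). The score of interferon response windows was 0.32 ± 0.08 against -0.09 ± 0.08, and that of matrix remodelling windows differed by 0.10, with the same permutation p. Averaged over TNFa, BMP target windows had a median of 0.31 with BMP4 (adjusted p = 0.00148; 0.0651 with an estimated correlation), chondrocyte markers 0.52 (0.00693; 0.145) and muscle and endothelial markers 0.42 (0.00511; 0.389). With fry the adjusted p of these 3 lists was 0.0108, 0.00146 and 0.418. The score of the last list ran from 0.06 to 0.84 in libraries with BMP4 and from -0.28 to 0.43 in those without (exact permutation p = 0.171). Without BMP4 replicate 2 lists passing in that comparison numbered 0 rather than 3, and without replicate 2 of the combined treatment 1. For the averaged TNFa comparison 1 rather than 2 passed without untreated replicate 1, TNFa replicate 2, BMP4 replicate 1 or replicate 1 of the combined treatment. Windows of Ccl2 with TNFa, and of Id3, Sox5 and Sox6 with BMP4, passed adjusted over the list alone. A Sox6 window that was lower with TNFa passed too. The Sox6 window plotted by group held 29.5 and 9.2 CPM with TNFa and 25.5 and 26.9 in untreated cells. It held 86.6 and 51.8 with both factors and 77.5 and 66.8 with BMP4. The plotted window thus showed no steady drop with TNFa, and the call of Sox6 as lower is not taken to concern it. In limma, with the libraries taken as unpaired, 0 of 14416 windows passed for either averaged comparison. At an unadjusted p under 0.05 there were 934 for TNFa (423 to 2160 without single libraries, highest without BMP4 replicate 1) and 294 for BMP4 (86 to 1001, highest without BMP4 replicate 2).

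With the first principal component as a covariate, 66 windows passed in the averaged TNFa comparison, 44 higher and 22 lower. Among the higher were the windows of Ccl2 (2.38 ± 0.26, SE), Pdgfb (2.37 ± 0.25), Herc1 (2.35 ± 0.31) and Mapt (2.14 ± 0.22), and windows assigned to Gdnf, a neurotrophic factor gene (1.86 ± 0.25), and Mefv, the gene of the inflammasome protein pyrin (1.88 ± 0.28). Among the lower were Speer5-ps1 (-1.89 ± 0.24), Aldh1a3, which encodes a retinoic acid synthesising enzyme (-1.72 ± 0.27), and the promoter of the channel gene Panx3 (-1.59 ± 0.25; chromosome 9, 37669344 to 37669468). Of the 35 splits of the libraries into 4 and 4, 2 passed as many: the real one, and one that set untreated replicate 1, both TNFa libraries and replicate 2 of the combined treatment against the rest, with 2471. That other split is the one by the sign of the second principal component, so it follows a structure of the samples and is not a random draw. The count of splits therefore does not decide on chance, which is not excluded. Without the covariate 0 windows passed for TNFa and for BMP4, so that 35 of 35 splits passed as many by construction, which says nothing about chance. The split of replicates 1 from replicates 2 passed the most, 3753 and 4994, which points to a structure of the samples.

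NF-kB target windows were higher in the 4 libraries with TNFa than in the 4 without. With each library thinned to 591988 tags in the matched windows, the mean difference over all windows was still 0.61. This bears only on uneven counts there, since the values were already scaled between libraries. The lists themselves were called at unequal depth, and the 4 libraries with TNFa were the shallower ones. Depth at that step therefore cannot be told apart from TNFa. The mean difference was 0.50 with the first principal component as a covariate and 0.79 in windows with identical coordinates. This argues against that component and against shifted windows as the whole cause. Of 35 splits, 4 had a camera p as small (real 9.99e-09, smallest other 3.77e-09), so chance is not excluded by that count. Each of the others differed from the real split by the exchange of a single library per side. They thus keep most of the grouping by TNFa and are not unrelated draws, so the count cannot decide on chance. The score parted the libraries by TNFa (exact permutation p = 0.0286, n = 4), which measures the pattern and not its cause, so TNFa treatment stays open, as does GC content, which was not tested.

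BMP target windows were higher in the 4 libraries with BMP4. The mean difference was 0.28 with the libraries thinned to equal tags in the matched windows, which again bears only on uneven counts there. It was also 0.28 with the first principal component as a covariate, which argues against that component as the whole cause. In windows with identical coordinates it was 0.19, which does not decide whether shifted windows contribute. Of 35 splits 1, the real one, had a camera p as small (0.000106, smallest other 0.00186). As 1 of 35 is the smallest share possible, and the splits disregard replicate numbers, this count does not exclude chance. The score had a permutation adjusted p of 0.16 over 28 tests. Without BMP4 replicate 2, 0 lists passed in the averaged BMP4 comparison. The score parted the libraries by BMP4 (exact permutation p = 0.0286, n = 4), which measures the pattern and not its cause. BMP4 treatment, shifted windows and chance therefore stay open.

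Replicates of one group lay far apart on the first principal component. Only the untreated and BMP4 pairs had total tags within 10% of each other, and their gaps were 64.6% and 98.6% of the component's range. This argues against unequal total depth for these pairs, which had already been seen to lie apart. Their tags in matched windows differed (1124455 and 1368770 untreated, 940016 and 1575145 with BMP4), so depth in the windows stays open. A correlation with total depth, tried first, was 0.435 (permutation p = 0.266). The treatment groups held 21.3% of its variance (permutation p = 0.733). The component followed the share of tags in windows (r = 0.866, exact permutation p = 0.00322; rank correlation 0.952, exact permutation p = 0.00114; r = 0.692, p = 0.11 without untreated replicate 2 and BMP4 replicate 2). Both come from the same tags, so an unequal share cannot be told apart from another cause that acts on both, and no biological explanation other than treatment was tested.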
